A study of Bubalus bubalis with 3 samples.

How the data were processed

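Small RNA was sequenced from adipose tissue of Chinese swamp buffalo (Bubalus bubalis) aged 6 months. The series held 1 group of 3 libraries, named here library 1, 2 and 3 after the numbers in the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol, small RNA libraries were made with an Illumina TruSeq kit by ligation of adaptors to both ends, cDNA was size-selected on a gel, and the libraries were sequenced on a HiSeq instrument. The protocols also name a kit for removal of ribosomal RNA. Bowtie, a short-read aligner, and the bovine genome build UMD3.1 are named per the submitters' processing notes, without a version or the step they served. The counting program, the miRNA annotation, the handling of reads that match several miRNAs and any filter are not given in the sources used here.

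The authors deposited TPM, per the file headers, as 1 table with a column per library and a row per miRNA name. Each deposited TPM column summed to the same total within rounding over the 622 listed names, so a value is a share of the reads assigned to these names. Values carry 1 decimal. All 3 value columns were mapped to samples by name and 0 columns were left unmapped. Of the 622 names, 396 were known bovine miRNAs and 226 carried only a pair of numbers (or X and a number), of which 44 ended in star. The meaning of these number names is not given in the sources used here. They are called candidate names below, were kept in the totals, and belonged to no list and no tested hairpin. The 7 with a mean of at least 10 TPM are among the tested names defined below. They thus entered the reference median of list levels and the pool of matched random lists.

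Depth was estimated from the values. In each column, values up to 30 TPM lay on whole multiples of 1 step, whatever the miRNA, so no scaling by miRNA length was visible. The step, taken as the worth of 1 read, was 0.146, 0.148 and 0.182 TPM in libraries 1, 2 and 3, which corresponds to 6860000, 6770000 and 5480000 reads, to the nearest 10000, in the listed names. Within the rounding of 0.1 TPM, 99.5% of 400, 100% of 371 and 100% of 378 low values lay on the step, against 68.6%, 67.7% and 54.8% for values placed at random. Because rounding is coarse against the step, reads are estimates and no count model was fitted. The floor, set at 3 reads, was 0.437, 0.443 and 0.547 TPM. On simulated tables of 622 names the fitted step was off by at most 0.0444%. Intervals for shares of reads are Wilson intervals at 95%, and the widest half-width among the 15 most abundant miRNAs was 0.0411 percentage points. Intervals and floors cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

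Values were analysed as log2(TPM + 1). A difference on that scale understates the change of a low miRNA. The tested names were the 166 with a mean of at least 10 TPM over the libraries. With 1 group, no contrast between groups could be made, and 4 descriptions were made instead. These were the abundance of each miRNA, the level of 18 miRNA lists, the difference between the arms of a hairpin, and the spread between libraries. Lists came from background knowledge and were fixed, with the tests and the rule for named miRNAs, before the data were examined. They covered adipogenesis (promoting and inhibiting), brown and beige fat (favouring and opposing), striated muscle, red blood cells, white blood cells, vessel wall, fibroblast stroma, liver and gut, epithelium, nervous tissue, the imprinted DLK1-DIO3 region, the let-7 and miR-30 families, miR-17-92 with its paralogues, HOX clusters, and the miR-2284 and miR-2285 family. A list member is the more abundant arm of a stem. Members below the minimum stayed in the level of a list, and planned names absent from the deposited names did not enter it. Several lists share members, among them 3 names in the promoting and favouring lists and 4 in the inhibiting and opposing lists.

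The level of a list is its median log2(TPM + 1) minus the median of the tested names in the same library. Its percentile was taken among 10000 random lists of the same size drawn from the 361 known stems. The spread of a list is the median SD over its members with at least 10 TPM, for the 14 lists with 3 or more such members, with its percentile among 10000 random lists of tested names matched on mean level (20 nearest neighbours). Percentiles describe these libraries and are not p-values. On simulated data, 12% of 100 random lists of 8 fell outside percentiles 5 to 95, and 100% of 100 lists with a doubled SD lay above percentile 95. The simulated members were independent and no other list size was simulated. These rates are therefore not known for smaller lists or for members that vary together.

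A hairpin was tested when names with both the 5p and the 3p ending were listed and the more abundant arm had a mean of at least 10 TPM. The difference of log2(TPM + 1) between the arms in each library was tested against 0 with limma's moderated test with a trend, two-sided, with Benjamini-Hochberg adjustment over the 20 hairpins and a threshold of 0.05. limma gave an infinite prior, so each hairpin received the pooled spread at its level in place of its own. On 100 simulated datasets of 20 hairpins, 2.5% of hairpins without a difference were called, 71.6% of those with a difference of 1 and 100% of those with a difference of 3 on the log2 scale. All simulated hairpins had the same spread (SD 0.566) before counting error, whereas the SD of the tested hairpins ran from 0.14 (miR-423) to 1.25 (miR-369). The simulation therefore does not give the rate of false calls when hairpins differ in spread.

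Named miRNAs are the 15 with the highest mean, the 6 hairpins with the largest difference in each direction among those called with the same sign in every library, the 8 largest and 4 smallest SD of log2(TPM + 1) among names with a mean of at least 100 TPM, and the 3 members of each list with the highest mean, with any member that answers a count of 5 or fewer. Alternatives were pseudocounts of 0.1 and 10, no minimum mean and a minimum of 100 TPM (1 and 100 TPM for the count of names), leaving out each library in turn, median-of-ratios size factors, removal of the most abundant miRNA, limma without a trend, and a minimum difference of 1 between arms. Removal of miR-10b before computing the spread, removal of 5 related names, list deviations after size factors and size factors for named means were added after the data were seen. Groups of 3 were not screened for outlying libraries.

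Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. A genome of the build named by the submitters was not used here, so no coordinates are given.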

Results

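miRNAs were measured by small RNA sequencing in adipose tissue of Chinese swamp buffalo, the draught and meat type of water buffalo in southern China, at 6 months of age. The series consisted of 1 group of 3 libraries. Values were TPM as deposited, each a share of the reads assigned to the listed names, and depth estimated from the steps between low values was 6860000, 6770000 and 5480000 reads in libraries 1, 2 and 3. Of 622 listed names, 541, 479 and 516 were above 0 in the 3 libraries, 154 reached 10 TPM in all 3, and 166 had a mean of at least 10 TPM. Those 166 comprised 159 known bovine miRNAs and 7 candidate names. The labels describe 3 adipose samples and do not say whether each came from a separate animal. SDs and p-values therefore measure only the spread between these samples, which may be technical.

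Which miRNAs made up the pool was asked first. miR-10b, encoded in the HOXD cluster, was the most abundant miRNA with 38.6% ± 11.3 of all TPM (SD, n = 3; 26.5%, 48.8% and 40.4% in libraries 1, 2 and 3). It was followed by miR-143, which is abundant in smooth muscle and promotes adipocyte differentiation in culture, with 21.0% ± 5.14. miR-26a, which favours adipocyte differentiation in cultured progenitors, came next with 9.69% ± 2.39. These 3 miRNAs held the first 3 ranks in the same order in all 3 libraries and together 69.2% ± 5.47 of TPM. The 10 most abundant miRNAs held 85.2% ± 5.14 of TPM (80.2% to 90.5%), and the first 15 held 90.6% ± 3.21.

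Ranks 4 to 10 were taken by miR-10a (3.24% ± 1.55 of TPM, SD, n = 3), miR-30a-5p (3.13% ± 0.400), miR-27b (2.24% ± 0.764), the endothelial miR-126-5p (2.02% ± 0.654), miR-100 (2.003% ± 0.499), miR-3600 (1.78% ± 0.725) and miR-99b (1.52% ± 0.259). They were followed by miR-191 (1.18% ± 0.331), miR-148a (1.10% ± 0.417), miR-181a (1.06% ± 0.374), let-7a-5p (1.06% ± 0.346) and the imprinted miR-127 (1.01% ± 0.679). Of these 15, 14 ranked within the first 15 of every library. The exception was miR-127, with ranks 10, 16 and 16 and 17805, 5154 and 7191 TPM in libraries 1, 2 and 3. Counting error of these shares, at most 0.0411 percentage points, was far below the spread between libraries, so neighbouring ranks after miR-26a whose means differ by less than their SD are not separated. Mature sequences of miR-10a and miR-10b, of miR-99 and miR-100 and within the let-7, miR-26, miR-30 and miR-199 families are nearly identical, and how reads were divided among them is not given in the sources used here.

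**Figure D1:**
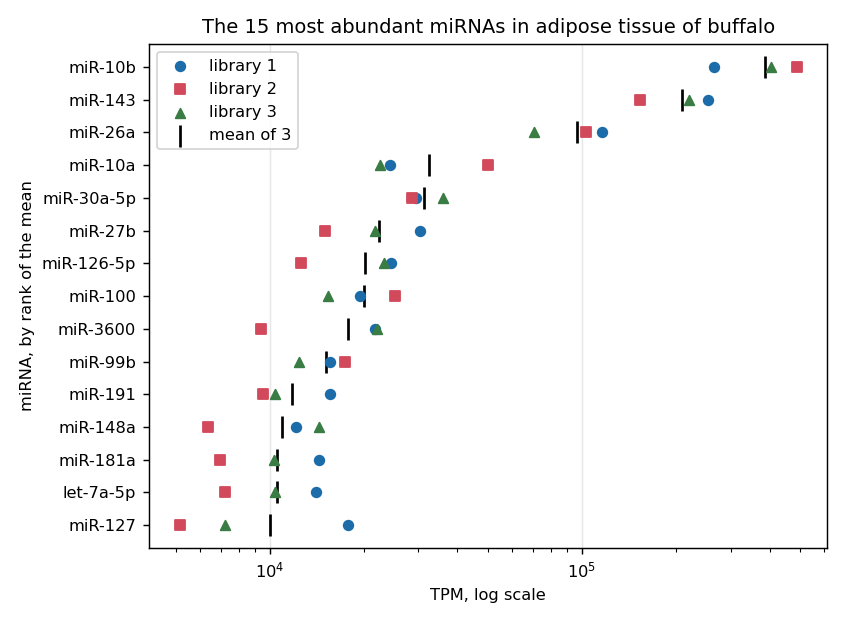
TPM of the 15 most abundant miRNAs on a log axis, with a point for each of the 3 libraries and a bar for their mean. miR-10b, miR-143 and miR-26a stand in the first 3 ranks of every library, in this order, and miR-127 ranges from 5154 to 17805 TPM.

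miRNAs with published roles in fat cells were examined as lists. The list that promotes adipocyte differentiation had all 19 of its members listed and 16 at a mean of at least 10 TPM, and summed to 37.5% ± 6.96 of TPM (SD, n = 3), carried by miR-143, miR-26a and miR-30a-5p. Its median lay 2.06 ± 0.08 log2 units above the median of the tested names. The list that inhibits differentiation had 21 of 23 planned names listed and 16 at 10 TPM or more. It summed to 4.56% ± 1.52 and lay 0.09 below the tested median (level -0.09 ± 0.30), led by miR-27b (22362 ± 7643 TPM), let-7a-5p (10559 ± 3459 TPM) and miR-125a (3916 ± 1398 TPM). The promoting median exceeded the inhibiting median by 2.14 ± 0.25 log2 units, in 3 of 3 libraries. Among random lists of the same size the promoting list stood at percentile 100 and the inhibiting list at 99.93.

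Lists linked to brown and beige fat stood lower. Of the list that favours brown or beige fat, 12 of 13 planned names were listed and 8 reached 10 TPM, with a level of -0.72 ± 0.30 (percentile 97.6). Its most abundant members were miR-26a (96857 ± 23850 TPM, SD, n = 3), miR-378 (2172 ± 890 TPM), which is encoded in the PGC-1β gene, and miR-193b (587 ± 249 TPM). Of the list that opposes brown or beige fat, 11 were listed and 7 reached 10 TPM, with a level of -1.05 ± 0.18 (percentile 95.8), led by miR-27b, miR-125b (1743 ± 625 TPM) and miR-27a-3p (592 ± 224 TPM).

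Markers of other cells and tissues differed widely in level. The vessel wall list, which consists of miR-143, miR-126-5p and miR-145 (961 ± 479 TPM, SD, n = 3), lay 7.05 ± 0.19 log2 units above the tested median (percentile 99.9), and shares miR-143 with the promoting list and miR-145 with the inhibiting list. The fibroblast stroma list lay 2.27 ± 0.22 above it (percentile 96.1), with miR-199a-3p at 1953 ± 881, miR-199b at 758 ± 371 and miR-214 at 53.2 ± 15.1 TPM. All 3 red blood cell miRNAs were present, miR-486 at 3482 ± 1204, miR-451 at 1061 ± 640 and miR-144 at 52.4 ± 33.4 TPM, with a level of 2.58 ± 0.68 (percentile 96.4). The white blood cell list had a level of -0.94 ± 0.93 (percentile 89.3) and 4 of 5 members at 10 TPM or more, led by miR-146a (559 ± 434 TPM), miR-150 (209 ± 146 TPM) and miR-142-5p (106 ± 111 TPM), while miR-223, a miRNA of myeloid cells, had 7.50 ± 3.77 TPM.

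Striated muscle, epithelial and nervous tissue markers were low. None of the 7 muscle miRNAs and none of the 6 listed epithelial miRNAs, of 7 planned, reached a mean of 10 TPM. The highest muscle members were miR-1 (9.27 ± 3.35 TPM, SD, n = 3), miR-133a (9.03 ± 7.15 TPM) and miR-499 (2.77 ± 1.10 TPM), and the list held 0.00236% of TPM, with a level of -5.87 ± 0.50 (percentile 23.2). The highest epithelial members were miR-141 (9.87 ± 2.91 TPM), miR-200a (1.03 ± 0.569 TPM) and miR-205 (0.767 ± 1.24 TPM), with a level of -6.67 ± 0.56 (percentile 7.04). Of 9 nervous tissue miRNAs, 3 reached 10 TPM, miR-128 (33.3 ± 19.99 TPM), miR-9-5p (16.9 ± 4.35 TPM) and miR-153 (12.7 ± 10.1 TPM), with a list level of -6.16 ± 0.29 (percentile 15.4). The liver and gut list had a level of -4.34 ± 0.07 (percentile 47.7). Its members miR-192 (1067 ± 358 TPM) and miR-194 (34.03 ± 13.2 TPM) were present, whereas the hepatocyte miRNA miR-122 had 0.367 ± 0.252 TPM, above the floor of 3 reads in library 1 only, and miR-885 had 0.633 ± 0.777 TPM.

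Families and clusters were compared in the same way. All 9 let-7 family members exceeded 100 TPM, led by let-7a-5p, let-7f (8083 ± 3222 TPM, SD, n = 3) and let-7i (4016 ± 1926 TPM), with a level of 3.66 ± 0.09 (percentile 99.96). All 6 miR-30 members did so too, led by miR-30a-5p, miR-30d (4672 ± 1379 TPM) and miR-30e-5p (3239 ± 1227 TPM), with a level of 3.02 ± 0.28 (percentile 99.8). Of the proliferation-linked miR-17-92 list, 9 of 14 members reached 10 TPM, led by miR-92a (1783 ± 529 TPM), miR-25 (1384 ± 592 TPM) and miR-93 (345 ± 148 TPM), with a level of -1.84 ± 0.13 (percentile 93.8). The HOX cluster list summed to 41.8% ± 12.5 of TPM, nearly all of it miR-10b and miR-10a, while miR-196b (72.9 ± 46.4 TPM) and miR-196a (48.9 ± 32.3 TPM) were far lower and miR-615 had 0.300 ± 0.173 TPM, for a median level of -1.27 ± 0.65 (percentile 86.4). Of 41 listed miRNAs of the imprinted DLK1-DIO3 region, 14 reached 10 TPM, led by miR-127, miR-411a (2854 ± 2119 TPM) and miR-409a (109 ± 84.3 TPM), with a level of -5.09 ± 0.38 (percentile 28.3). Of 20 listed names of the ruminant miR-2284 and miR-2285 family, 1 reached 10 TPM, miR-2284x at 25.9 ± 14.98 TPM, ahead of miR-2285f (9.53 ± 3.46 TPM) and miR-2284y (5.37 ± 3.29 TPM), with a level of -6.82 ± 0.48 (percentile 0.01).

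Of the 18 lists, 6 lay above the tested median in all 3 libraries, the promoting, red blood cell, vessel wall, fibroblast stroma, let-7 and miR-30 lists, and 10 lay below it in all 3. With 3 libraries an exact two-sided sign-flip permutation test cannot go below p = 0.25, so these levels are descriptions. The reference median depends on the minimum: with no minimum mean 14 lists lay above it in all 3 libraries, and with a minimum of 100 TPM 3 did and the promoting list turned to -0.08.

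**Figure D2:**
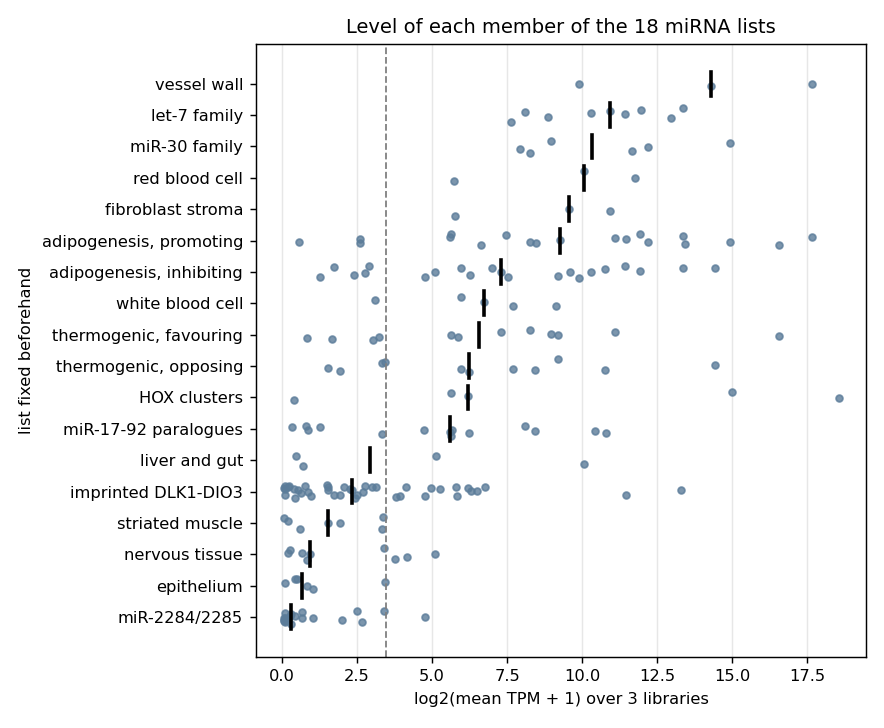
Each point is a member of 1 of the 18 lists at its log2(mean TPM + 1) over 3 libraries, the black bar is the list median, and the dashed line marks 10 TPM. Vessel wall, let-7 and miR-30 members lie at the high end, and no muscle or epithelial member passes 10 TPM.

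The arms of a hairpin arise in equal number from a precursor, and which arm had more reads was asked within each library. The arms differ in sequence, so a difference in reads may come from library preparation as well as from retention of an arm. These were not told apart. Both arms were listed for 33 hairpins and 20 were tested, of which 11 had more of the 5p arm and 6 more of the 3p arm at an adjusted p below 0.05 in limma. Differences of log2(TPM + 1) were largest towards 5p for miR-99a, 11.56 ± 0.91 log2 units (SD, n = 3), with 5066 ± 1754 TPM for 5p and 0.633 ± 0.404 TPM for 3p. Next came let-7a (10.53 ± 0.64), miR-21 (10.22 ± 0.19), miR-30b (8.21 ± 0.49), miR-6119 (6.75 ± 0.27) and miR-126 (4.61 ± 0.15), whose 3p arm still had 811 ± 200 TPM. Towards 3p they were largest for miR-365 (-6.10 ± 0.39), followed by miR-27a (-5.93 ± 0.60), miR-22 (-4.98 ± 0.28), miR-369 (-4.33 ± 1.25), miR-199a (-2.40 ± 0.25) and miR-193a (-1.31 ± 0.25), each with the same sign in 3 of 3 libraries. For miR-369 the difference rests on about 510 reads of 3p and 1 read of 5p, a ratio of 510 with a 95% exact counting interval of 91.1 to 20183.

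No difference between the arms was called for miR-142 (0.46 ± 0.16, limma adjusted p = 0.114), miR-411c (0.39 ± 1.11, adjusted p = 0.276) and miR-423 (-0.21 ± 0.14, adjusted p = 0.391). miR-411c had more 5p in libraries 1 and 3 (1.42 and 0.55) and more 3p in library 2 (-0.79). The largest adjusted p among the called hairpins, 0.000141, was that of miR-362, whose call was lost without library 3 (adjusted p = 0.0540). The p-values lean on the spread pooled over hairpins, and the order of the hairpins depends on the pseudocount: with 0.1, miR-369 (-7.13) passed miR-365 (-7.07) and miR-21 (10.79) passed let-7a (10.74), and with 10, let-7a (9.32) passed miR-99a (8.83) and miR-27a (-4.97) and miR-22 (-4.51) passed miR-365 (-3.78). With 10, miR-369 fell to -1.66, behind miR-199a (-2.36).

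**Figure D3:**
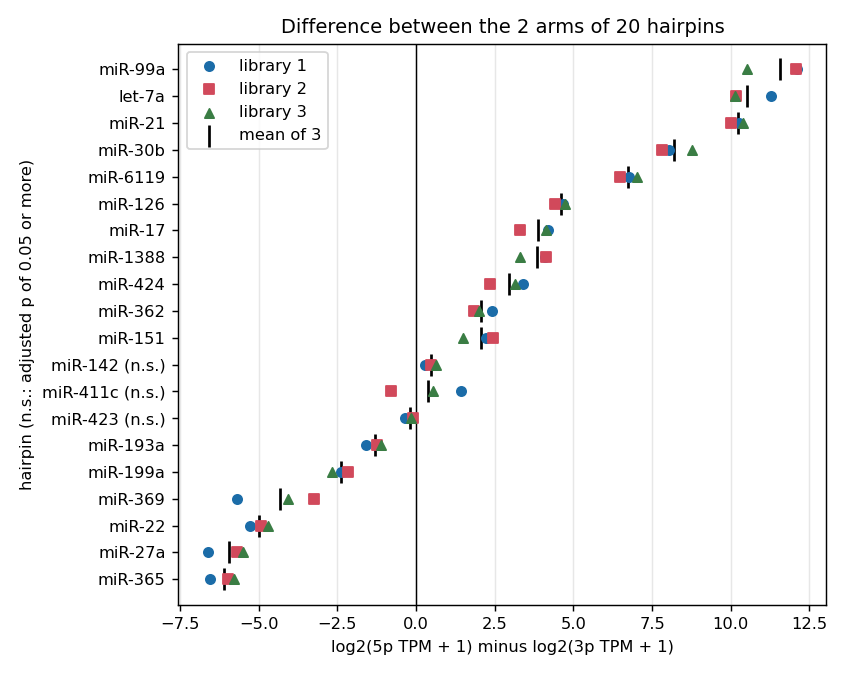
Difference of log2(TPM + 1) between the 5p and the 3p arm of 20 hairpins, with a point for each of 3 libraries and a bar for the mean. In 11 hairpins the 5p arm and in 6 the 3p arm was in excess, and the points of miR-411c lie on both sides of 0.

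How far the 3 libraries differed was described over the 166 tested names. Pearson correlations of log2(TPM + 1) across miRNAs, which are not independent replicates, were 0.978, 0.979 and 0.983 for libraries 1 and 2, 1 and 3, and 2 and 3, and Spearman correlations were 0.969, 0.964 and 0.973. The median SD of log2(TPM + 1) was 0.66. Library 2 lay below the mean of the libraries for 94.0% of the tested names. Size factors were 1.36, 0.602 and 1.21 (0.45, -0.73 and 0.27 on the log2 scale), and after division by them the median SD was 0.31.

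Among names with a mean of at least 100 TPM the largest SD of log2(TPM + 1) was that of the white blood cell miRNA miR-142-5p (1.46), with 233, 32.3 and 53.4 TPM in libraries 1, 2 and 3. It was followed by miR-146b (1.23), the red blood cell miR-451 (1.23; 1486, 325 and 1371 TPM), miR-139 (1.20), miR-146a (1.12), the imprinted miR-409a (1.12) and miR-411a (1.11), and miR-150 (1.00). The smallest SDs were those of miR-204 (0.06), miR-148b (0.15), miR-30a-5p (0.18) and miR-374a (0.21). Single libraries set several of these values. Without library 1 the SD of miR-142-5p was 0.50, and without library 2 that of miR-451 was 0.08. After size factors, 3 of these 8 and 0 of these 4 remained in the corresponding ranking. The largest SD was then that of miR-10a (1.27), and the smallest that of miR-423-5p (0.02).

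Of the 14 lists with enough tested members, 4 varied more than 95% of matched random lists. These were the imprinted DLK1-DIO3 list (median SD 1.11 against 0.69 in matched lists, percentile 99.97), the red blood cell list (1.12 against 0.67, percentile 99.1), the white blood cell list (1.06 against 0.73, percentile 97.6) and the HOX list (0.94 against 0.64, percentile 97.9). After size factors the imprinted list (percentile 99.94) and the HOX list (99.2) stayed above 95, and the red (91.9) and white blood cell lists (92.4) did not. Single libraries decided the percentiles before size factors. Without library 1 the imprinted list fell to percentile 29.6 and the white blood cell list to 5.89. Without library 2 the red blood cell list fell to 65.2 and the HOX list to 19.2. Percentiles after size factors were not computed with a library left out.

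Relative to the size factors, 12 of the 14 tested imprinted miRNAs lay above their mean in library 1, with a median deviation of 0.70 there and -0.34 and -0.35 in libraries 2 and 3. The exceptions, miR-379 (-0.60) and miR-655 (-0.03), were named after their values were seen. The median of the 4 tested white blood cell miRNAs was highest in the same library (0.68, -0.24 and -0.49), with 4 of 4 above their mean in library 1. miR-223, listed below the minimum, was highest in library 2 (0.26, 0.54 and -0.79). The median of the red blood cell miRNAs was lowest in library 2 (0.32, -0.53 and 0.04), where miR-451 (-0.69) and miR-144 (-0.53) lay below their mean and miR-486 (0.14), the most abundant of the 3, lay above it. Within the HOX list miR-10a and miR-10b deviated by 1.46 and 1.11 in library 2, and miR-196a and miR-196b by -0.90 and -0.70. The promoting list (percentile 8.67 after size factors), the inhibiting list (72.8), the lists favouring (68.4) and opposing brown or beige fat (59.1), and the nervous tissue (65.1), vessel wall (42.3), fibroblast stroma (29.8), let-7 (40.4), miR-30 (46.7) and miR-17-92 (7.83) lists lay between percentiles 5 and 95 in spread, with and without size factors. Before size factors some of them passed these ends under other settings. With a pseudocount of 10 the nervous tissue list lay at 95.7. Without library 1 the favouring (98.4) and nervous tissue (97.3) lists lay above 95 and the inhibiting (2.31) and opposing (1.74) lists below 5, and without library 2 the inhibiting (96.3) and opposing (97.0) lists lay above 95 and the fibroblast stroma list (3.58) below 5.

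**Figure D4:**
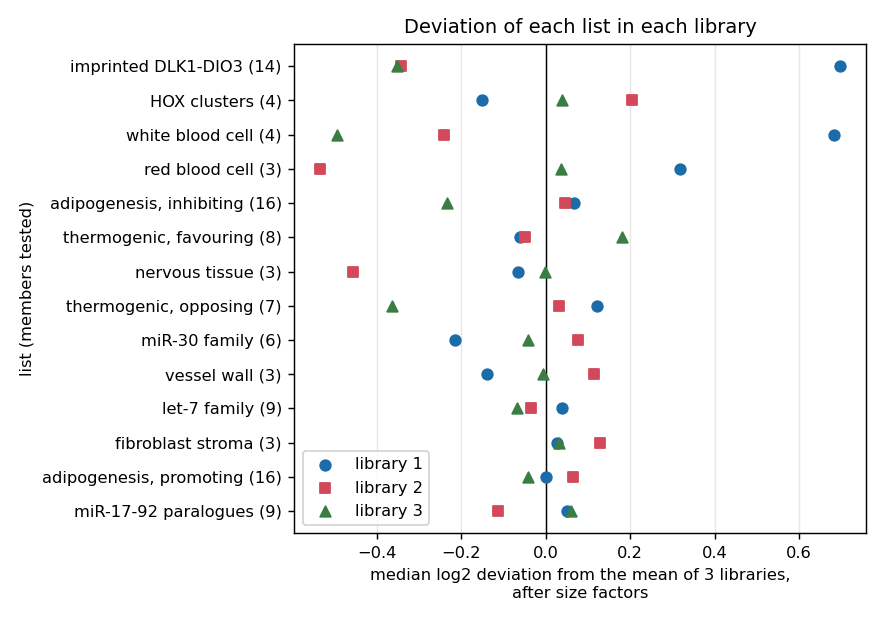
Median log2 deviation of each list from its mean over 3 libraries after size factors, with a point per library and the number of tested members in parentheses. The medians of tested imprinted (0.70) and white blood cell miRNAs (0.68) are highest in library 1, and the median of red blood cell miRNAs is lowest in library 2 (-0.53), with miR-486 above its mean there.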

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

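Among the names that belonged to no list and no tested hairpin, 7 candidate names, which carry no known miRNA name, had a mean of at least 10 TPM, above the limit of 3 reads in each library. Candidate 12_4647 had a mean of 40.2 ± 20.6 TPM (SD, n = 3), with 43.3, 18.2 and 59.1 TPM in libraries 1, 2 and 3. Candidate 7_28048 had 39.6 ± 13.4 TPM and was highest in library 2 (36.0, 54.4 and 28.3 TPM). Candidates 6_27184, X_32414, 4_25272 and 13_6388 had means of 18.4, 17.8, 15.4 and 14.1 TPM. Candidate 26_20059_star had a mean of 12.5 ± 11.1 TPM, with 23.7, 1.5 and 12.4 TPM in the 3 libraries. All 226 candidate names together held 0.0330% ± 0.00863 of TPM, and 50 of them had at least 3 reads in every library. What these names stand for is not given in the sources used here, and no explanation was tested. The libraries form 1 group of 3, so none was screened as lying far from the others.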

How the results depend on the processing

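Removal of miR-10b before computing the spread, removal of 5 names, size factors for named means and list deviations after size factors were chosen after the data were seen. The counts of 11 and 6 hairpins stayed within 1.5 times under every alternative run. Names at the minimum in all 3 libraries numbered 267 at 1 TPM and 79 at 100 TPM in place of 154. Once miR-10b was taken out, the 10 most abundant of the rest held 78.2% of the remaining TPM. The median SD of 0.66 was 0.59 with a pseudocount of 10, 0.37 with no minimum mean, 0.60 with a minimum of 100 TPM and 0.31 with size factors. It was 0.505 without miR-10b, 0.42 without the 5 names, and 0.28 to 0.79 when each library was left out in turn. A larger pseudocount, or names near 0 taken in, shrinks log2 differences by construction. The cause of the other shifts was not tested. Lists above the tested median in all 3 libraries numbered 14 with no minimum mean and 3 with a minimum of 100 TPM in place of 6, and lists above percentile 95 in spread numbered 2 with that minimum, where the red blood cell and HOX lists have 2 tested members each and were not evaluated, and 2 with size factors, where the cause was not tested, in place of 4. Without a minimum mean the reference median drops by construction, and the levels turned to 5.55 (favouring) and 5.23 (opposing brown or beige fat), 0.41 (muscle), 1.94 (liver and gut), 0.12 (nervous tissue), 1.18 (imprinted), 4.44 (miR-17-92) and 5.01 (HOX). The inhibiting and white blood cell levels, of mixed sign among the libraries, turned to 6.19 and 5.34 there. With a minimum of 100 TPM it rises, and the promoting list turned to -0.077. The uncalled arm difference of miR-411c ranged from -0.12 to 0.98 when each library was left out, and the call of miR-193a was lost against a minimum difference of 1 (limma adjusted p = 0.173). Of the other values, 20 SDs of single miRNAs and 40 list levels, the inhibiting and white blood cell ones included, moved, and 8 list percentiles crossed 5 or 95 towards and 7 away from the ends. No pairing of samples between groups was possible because the series has 1 group. Rounding to 0.1 TPM limits values near the floor of 3 reads.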

Other observations

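All lists and tests in this part were chosen after the data were seen, except the imprinted, HOX, blood cell, fibroblast stroma and promoting lists. Deviations are log2 differences from the mean of the 3 libraries after size factors.

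The miR-424/450 cluster, which lies on the X chromosome in human and mouse, was represented by miR-450b (82.4 ± 72.7 TPM, SD, n = 3), miR-450a (54.3 ± 56.7 TPM) and miR-424-5p (30.7 ± 21.2 TPM), with miR-542-5p and miR-503-3p at 2.10 and 1.03 TPM. Its 3 tested members were each above their mean in library 1, with median deviations of 0.98, -0.61 and -0.16 in libraries 1, 2 and 3, and a spread at percentile 99.3 of matched lists after size factors and 100 before. The miR-29 family, which targets collagen transcripts, had miR-29a at 414 ± 90.1, miR-29c at 166 ± 63.2 and miR-29b at 29.9 ± 8.04 TPM, with a spread at percentile 2.04 of matched lists before and 37.3 after size factors. miR-103 (615 ± 301 TPM) and miR-107 (97.0 ± 59.8 TPM), which lie in introns of PANK genes and belong to the promoting list, had median deviations of 0.33, -0.37 and 0.04.

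miR-10a, miR-10b, miR-99a-5p, miR-99b and miR-100 held 58.8% of TPM in library 2 against 33.1% and 45.7% in libraries 1 and 3. miR-10b alone held 48.8%, against 26.5% and 40.4%. In deposited TPM each was highest in library 2 except miR-99a-5p (6159.5, 5995.3 and 3042.3 TPM in libraries 1, 2 and 3). After size factors all 5 lay above their mean in library 2, by 0.95 to 1.46. Shared control of the HOX clusters as a whole is argued against by miR-196a and miR-196b, which lie in HOX clusters too and deviated by -0.80 on average in library 2. This comparison was chosen after their values were seen and rests on library 2 alone. Control of only part of a HOX cluster was not tested. Shared primary transcripts of miR-99 and miR-100 are argued against by their partners let-7c, let-7e, miR-125a and miR-125b, of which the highest deviated by 0.28 (SD of the 4, 0.19). A preference for related sequences in library preparation cannot be told apart from a difference in the tissue, because 0 names of related sequence were left to test, although miR-1271 (1.27) and miR-379 (1.10), of other families, deviated as far. No difference between conditions was tested, since the design has 1 group.

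Most names were lower in TPM in library 2, with a median difference of -1.047 log2 units from the mean of libraries 1 and 3 (95% bootstrap interval over names, which are not independent, -1.14 to -0.99). A larger share taken by miR-10b accounts for part of it only, since the difference was -0.70 (-0.77 to -0.63) after that miRNA was taken out and values were rescaled. Taking out all 5 names above left -0.55 (-0.61 to -0.47). Library 2 had 6770000 estimated reads in the listed names, more than the 5480000 of library 3. The number of reads does not set the size of a share, so no conclusion on shallow sequencing is drawn from it. Values are shares, so -0.55 need not mean a loss of the remaining names. The most abundant of these, miR-143, miR-26a and miR-30a-5p, lay above their mean in library 2 after size factors, by 0.31, 0.86 and 0.61. Because the shares of a library sum to a fixed total, lower shares of most names are offset by larger shares of others by construction. Which further names account for the -0.55 was not tested, nor was any biological explanation.

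Most tested imprinted miRNAs of the DLK1-DIO3 region (12 of 14) and the 4 tested white blood cell miRNAs were higher in library 1. The median deviation of the imprinted list in library 1 was 1.14 before and 0.698 after size factors, the latter at percentile 100 of matched random lists. The pattern was itself seen in the values after size factors, so these values are no separate test of scaling between libraries. Whole blood left in the tissue is argued against relative to library 3 only if it raised red and white cell miRNAs alike. The 4 tested white cell miRNAs exceeded library 3 by at least 1.047, and miR-451, miR-486 and miR-144 by -0.06, 0.18 and 0.46. A miRNA that also comes from other cells of the tissue would rise less, so a part played by blood is not excluded. All 3 red cell miRNAs lay above their mean in library 1, with a median of 0.32. Whole blood stays open relative to library 2, where the 4 white cell miRNAs were higher by 0.48 to 1.65 and the red cell miRNAs by 1.01, -0.12 and 1.03. A larger share of fibroblast stroma is argued against for the imprinted list only, by miR-199a-3p, miR-199b and miR-214. They deviated by 0.03, 0.29 and -0.24 in library 1, with a median of 0.0275 (SD 0.26). Their directions differed, so a smaller difference in stroma is not excluded. For the white blood cell miRNAs it was not tested. A difference in the share of white blood cells without red cells was not tested, nor was any difference between conditions.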
